A study of Homo sapiens with 6 samples.

How the data were processed

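Expression was measured in 6 samples of the human embryonic stem cell line H1, 3 undifferentiated (hESC) and 3 after spontaneous differentiation to a meso-endoderm phenotype (hESC-MEC). Groups and replicate numbers came from the sample titles, and every value column carried a sample, with 0 columns left unassigned. Per the labels, total RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised to Affymetrix arrays, 1 array per sample. The deposited values were on the log2 scale, 1 per probe set and array. The submitters' processing notes name RMA and limma without a role or version. RMA corrects background, applies quantile normalization and summarises probes on the log2 scale, which matches the range and the nearly equal medians of the 6 columns; the scanner and its settings are not given in the sources used here. Quantile normalization makes the distributions of arrays alike, so a change in total RNA per cell cannot be read from these values.

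The 54675 probe sets were named through the platform annotation. Of these, 41097 had 1 gene symbol, 1801 had several, 11721 were not listed and 62 were Affymetrix controls, of which 6 are also counted among those with 1 symbol. Symbols were updated through Entrez gene identifiers with a RefSeq gene table of assembly GRCh38.p14, which matched 41043 probe sets and was used only for names and for the chromosome a gene lies on. Only probe sets with 1 symbol entered the comparison, giving 19775 genes. A gene with several probe sets (10523 genes) was represented by the one with the highest mean over all 6 arrays, and no dim gene was removed. The arrays give no detection calls, so the 95th percentile of the mean level of 102 olfactory receptor genes, 7.46, served as the background level. The number of arrays limits the precision.

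Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05; a count of larger changes also required an absolute log2 fold change of at least 1. The test, 26 gene lists and the rule for named genes were fixed before the data were examined. Of 561 list genes, 492 were measured, and the others were not analysed here. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and with an estimated correlation and fry as alternatives. With an estimated correlation, camera takes the 4 residual degrees of freedom of the fit, which makes passing hard whatever the correlation. The rule named the 8 largest rises and the 8 largest falls among genes past the threshold whose groups did not overlap, up to 3 members of largest change per list among those past the threshold, and, whatever their result, POU5F1, NANOG, SOX2, AFP, ALB, GATA4, VIM and CDH1. It gave 90 genes. A further 145 genes were named after their values were seen, namely members of lists where 5 or fewer rose, fell or did not pass, and examples of gene families and copies. A first version of 86 genes was cut to 51 after their dependence on the processing had been seen. The cut lowered the reversals from 25 to 7, but it was undone, and every small count in the lists was then named. Another 6 genes, members of the early mesoderm list that did not pass, were added later and are not among the 145.

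Other settings left out dim genes (the lowest 40%, or those at or below the olfactory receptor level), used eBayes with trend and robust, centred arrays on their medians, repeated quantile normalization, weighted the arrays, took the mean or the lowest of a gene's probe sets, left out probe sets marked _x_at or _s_at, added the replicate number as a block, left out each array in turn, or tested all probe sets. The pseudocount alternative was not needed, since the values were already logarithms.

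The fit was tested on simulated data for the comparison of hESC-MEC with hESC over 19775 genes, with 50 genes changed at each of several sizes. It recovered 16% of genes changed by 0.25 on the log2 scale, 64% at 0.5 and 100% at 1 and at 2, with 4 false among 144 calls, and 2 of 200 unchanged lists had a camera p below 0.05. Far fewer genes changed there than in the data (59.2%), so its adjusted threshold was stricter and these rates do not carry over. Noise was drawn independently for each gene, so the unchanged lists do not check camera for correlated genes. Groups of genes by symbol (21 families) were defined by patterns written before their values were computed and narrowed after a first look, to drop genes that were not members.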

Results

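Total RNA of 6 samples of the human embryonic stem cell line H1 was labelled with biotin and measured on 6 Affymetrix expression arrays. Undifferentiated cells (hESC) gave 3 arrays, and cells that had differentiated spontaneously to a meso-endoderm phenotype (hESC-MEC) gave the other 3. The titles call the 3 arrays of a group biological replicates without saying whether they came from separate cultures, so the p-values below measure the spread between these arrays, which may be partly technical. The deposited values were log2 expression levels, with array medians between 6.29 and 6.32. Over 19775 genes, Pearson's r between arrays of one group lay between 0.996 and 0.998 and between arrays of different groups between 0.852 and 0.855. The first principal component separated the groups and held 97.1% of the variance. The number of arrays limits the precision of each value. The 3' minus 5' log2 signal of ACTB control probe sets was 0.904 ± 0.140 (SD, n = 3) in hESC and 0.611 ± 0.035 (SD, n = 3) in hESC-MEC, a difference of 0.293 ± 0.084 (SE).

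The comparison asked how expression differed between the differentiated cells and the stem cells they came from. Genes of the extracellular matrix and of mesenchymal cells were the ones that rose most. LUM, a small matrix proteoglycan, rose 435-fold (log2 fold change 8.76 ± 0.10, SE, n = 3 arrays per group), and COL3A1, which encodes the chain of type III collagen, rose 406-fold by the probe set used (its 5 probe sets had log2 fold changes from 0.18 to 9.09, and the call ended with the one of lowest mean, limma adjusted p = 0.243). Regulators of the stem cell state and genes of epithelial adhesion fell most: LIN28A, an RNA-binding protein that blocks maturation of let-7 microRNAs, was 693-fold lower (log2 fold change -9.44 ± 0.064), and CDH1, the adhesion molecule E-cadherin, was 269-fold lower (-8.07 ± 0.071). Genes of mitosis and DNA replication were lower as well, whereas markers of liver and of definitive endoderm stayed mostly below the background level in both groups.

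Of the 19775 genes, 11698 (59.2%) differed between the groups at a limma adjusted p below 0.05, with 5072 higher and 6626 lower in hESC-MEC. The change was at least 2-fold for 3966 genes, 1865 higher and 2101 lower (4151 higher and 3822 lower when all probe sets were tested, so the balance turned), and at least 16-fold for 246 genes, 153 higher and 93 lower. All 3 arrays of one group lay above all 3 of the other for 12715 genes, where chance gives 10% of genes for 3 against 3. Fold changes below are log2 values of hESC-MEC over hESC with the standard error of the limma fit, n = 3 arrays per group. The background level was taken as the 95th percentile of the mean levels of 102 olfactory receptor genes, 7.46 on the log2 scale.

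By the probe set of highest mean for each gene, and besides LUM and COL3A1, the 8 largest rises were those of POSTN (periostin, 8.32 ± 0.078), MMP1 (interstitial collagenase, 8.16 ± 0.077), LAMA4 (a laminin chain, 7.79 ± 0.10), LOX (lysyl oxidase, which crosslinks collagen, 7.72 ± 0.062), PTX3 (a secreted pentraxin, 7.63 ± 0.086) and ASPN (asporin, 7.31 ± 0.064). Besides LIN28A and CDH1, the 8 largest falls were those of OTX2 (a homeobox factor of the epiblast and forebrain, -8.77 ± 0.073), ZIC2 (a zinc finger factor, -8.53 ± 0.10), APELA (a peptide ligand of the apelin receptor, -8.32 ± 0.079), TRIM71 (-8.29 ± 0.14), EPCAM (an epithelial adhesion molecule, -7.65 ± 0.082) and LRRN1 (-7.25 ± 0.10). The limma adjusted p of these 16 genes was at most 3.07e-10. Over a gene's probe sets the rise ranged from 3.83 to 8.76 for LUM, from 0.31 to 8.32 for POSTN, from 0.84 to 7.79 for LAMA4, from 2.05 to 7.72 for LOX and from 5.42 to 7.31 for ASPN, and the fall from -8.77 to -6.19 for OTX2 and from -8.07 to -1.97 for CDH1. Another choice of probe set would change the order. Each of the 8 genes that rose was below background in hESC, and each of the 8 that fell was below background in hESC-MEC, so the size of these folds depends on the level the array reads for a transcript near its floor, as does any fold below whose lower group lay below background. In the lists below, wherever 5 or fewer members rose, fell or did not pass, those members are named; the ones in sentences marked "after the fact" lay outside the naming rule and were chosen after their values were seen.

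**Figure D1:**
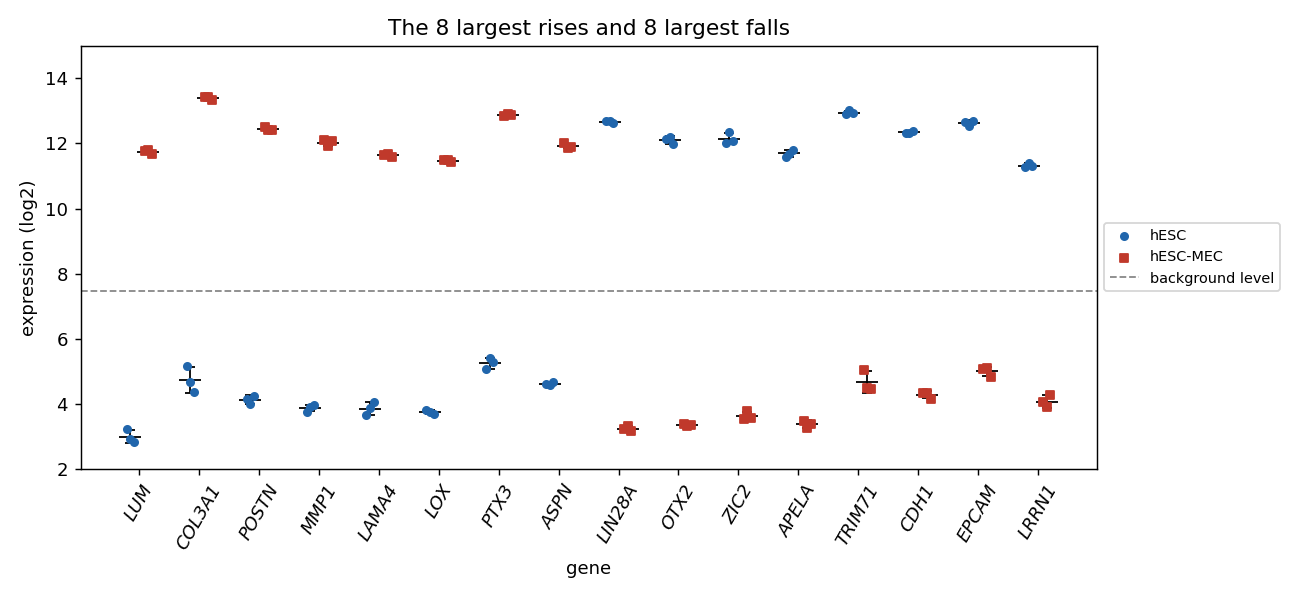
Expression on the log2 scale (vertical axis) of the 8 genes with the largest rise and the 8 with the largest fall (horizontal axis); circles are the 3 hESC arrays, squares the 3 hESC-MEC arrays, short bars with whiskers the mean and SD, and the dashed line the background level of 7.46. For every gene shown, one group lay below that line and the other above it.

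Among 31 measured pluripotency factors and stem cell markers, 27 fell, 2 rose and 2 did not pass, with the same counts adjusted over the list alone. LIN28A, TRIM71 and DPPA4 (-7.24 ± 0.074) fell most. SOX2 fell by 4.47 ± 0.066 (-8.52 to -1.20 over its 4 probe sets) and NANOG fell by 3.59 ± 0.076 (-3.59 and -0.68 over its 2 probe sets), and the number of members above background was 27 in hESC and 6 in hESC-MEC. The mean log2 fold change of the list was -3.25, lower than that of other genes by camera (limma adjusted p = 1.66e-09), which did not hold with an estimated correlation (adjusted p = 0.0509). After the fact, KLF4 (3.16 ± 0.15) and THY1 (1.30 ± 0.074) rose, and CD9 and FOXD3 did not pass. CD9 was lower and passed with the probe set of lowest mean (-0.39), and FOXD3 was lower and passed with the mean over probe sets (-0.96) and with the probe set of lowest mean (-2.51, limma adjusted p = 1.56e-07), so its result depends on the probe set. A value for POU5F1 (OCT4) was not analysed here, because its probe set named several genes. Probe sets of its copies POU5F1P3, POU5F1P4 and POU5F1B, picked after their values were seen and able to bind related transcripts, had log2 fold changes of -5.37 ± 0.095, -4.69 ± 0.072 and -3.26 ± 0.078, and all 3 fell.

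All 20 measured epithelial junction genes fell, also when adjusted over the list alone, among them CDH1, EPCAM and ESRP1 (an epithelial splicing regulator, -6.65 ± 0.059). Their mean was -3.33 (camera adjusted p = 2.89e-10 by limma; adjusted p = 0.0892 with an estimated correlation). Of 10 keratins, KRT19 (-4.93 ± 0.10), KRT8 (-3.92 ± 0.10) and KRT18 (-3.91 ± 0.084), which form the filaments of simple epithelia, fell, 1 rose and 6 did not pass, counts that were unchanged when adjusted over the list alone. The mean of the keratins was -1.20 and their median 0.040, opposite in sign, and camera gave an adjusted p of 0.526 (limma). Named after the fact, the keratin that rose was KRT80 (0.52 ± 0.067).

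Of 37 mesenchymal and extracellular matrix genes, 35 rose, 1 fell and 1 did not pass, and the counts adjusted over the list alone were the same. LUM, COL3A1 and POSTN led the list, and VIM, the intermediate filament vimentin, rose by 2.33 ± 0.085 from a level of 11.73 ± 0.17 (SD, n = 3) in hESC. The mean was 4.36 (camera adjusted p = 3.27e-21 by limma; adjusted p = 0.0553 with an estimated correlation), and 17 members were above background in hESC against 36 in hESC-MEC. Fibroblasts, which can serve as feeder cells in stem cell culture, also express many genes of this list. Named after the fact, the gene that fell was SNAI1 (-0.34 ± 0.10) and the one that did not pass was TAGLN.

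Of 26 genes of early mesoderm and cardiac mesoderm, 17 rose, 3 fell and 6 did not pass, as also when adjusted over the list alone. The largest rises were those of PDGFRA (the platelet-derived growth factor receptor alpha, 6.08 ± 0.088), FOXF2 (5.07 ± 0.057) and TWIST1 (5.04 ± 0.30). The mean was 1.37 (camera adjusted p = 2.46e-04 by limma; adjusted p = 0.0892 with an estimated correlation). After the fact, ACTC1 (-2.90 ± 0.16), MYL7 (-0.92 ± 0.086) and MYH6 (-0.32 ± 0.090) fell. HAND1, TBX5, ISL1, NKX2-5, GATA5 and WT1, also picked after the fact, did not pass. The list joins early mesoderm with cardiac genes, so its mean does not show that cardiac genes rose as a group. Among 16 genes of the BMP and TGF-beta list, 9 rose, 4 fell and 3 did not pass (9 rose and 5 fell adjusted over the list alone). This list joins targets with ligands, such as BMP2 and BMP7, and antagonists, such as GREM1, so its mean does not measure the activity of either pathway. GREM1, a secreted BMP antagonist, rose about 128-fold (SE 0.42 on the log2 scale) from a level below background, so the fold is not exact, TGFB1I1 rose by 3.59 ± 0.080 and LTBP2 rose by 3.52 ± 0.064. After the fact, ID4 (-2.87 ± 0.062), ID3 (-1.66 ± 0.065), ID1 (-1.19 ± 0.058) and BAMBI (-0.54 ± 0.11) fell, and BMP2, ID2 and BMP7 did not pass. BMP7 was lower and passed with the mean over probe sets (-0.89) and with the probe set of lowest mean (-1.35, limma adjusted p = 1.66e-07), and BMP2 was lower and passed in 6 other settings. The list's mean of 1.20 did not pass the camera test (limma adjusted p = 0.056), although it passed without hESC replicate 1 (adjusted p = 0.037), after median centring (0.0466) and without probe sets marked _x_at or _s_at (0.0212). The hESC arrays differed more than usual for GREM1, at 6.47, 4.38 and 4.94, and for TWIST1, at 5.53, 4.47 and 5.94, against a median SD over genes of 0.091 in hESC.

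**Figure D2:**
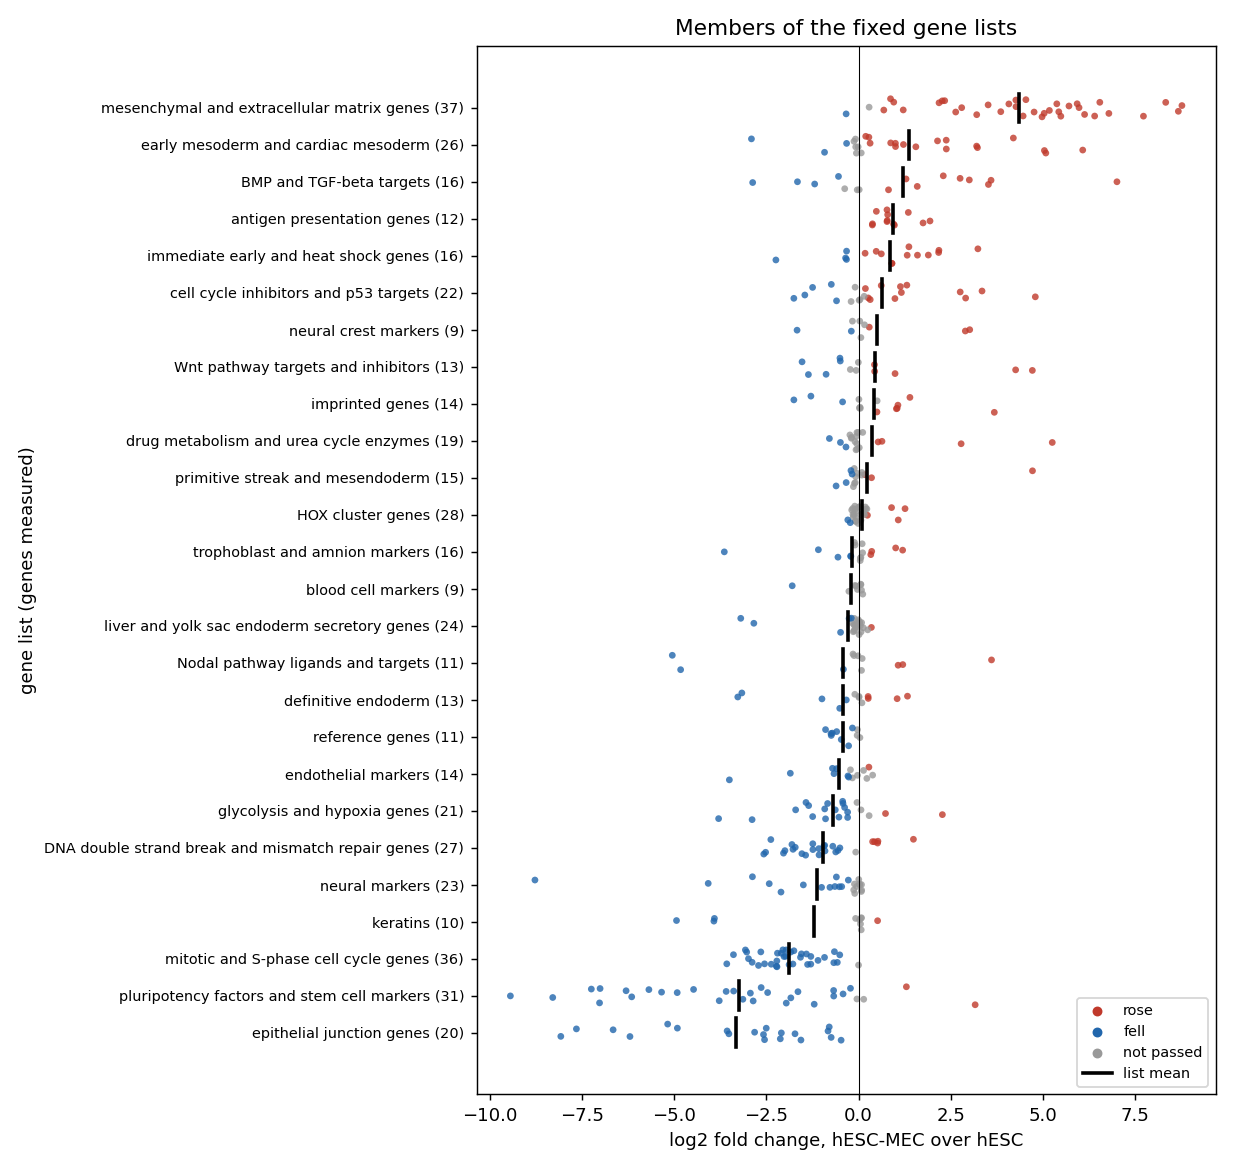
Log2 fold change of hESC-MEC over hESC (horizontal axis) for each measured member of the 26 gene lists (vertical axis, number of measured genes in parentheses); red points rose, blue points fell and grey points did not pass at an adjusted p of 0.05, and the black bar is the list mean. The mesenchymal list has the highest mean, 4.36, and the epithelial junction list the lowest, -3.33.

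Primitive streak and endoderm genes changed in both directions, but most lay below background. Above it were 1 of 15 streak genes in hESC and 2 in hESC-MEC, and 4 and 3 of 13 definitive endoderm genes. Small changes of the others lie near the floor of the array. Of 15 primitive streak and mesendoderm genes, 3 rose, 4 fell and 8 did not pass (2 rose and 2 fell adjusted over the list alone). DKK1, a secreted Wnt antagonist, rose by 4.71 ± 0.087, whereas SP5 rose by 0.35 ± 0.10 and EVX1 fell by 0.61 ± 0.070, both below background in both groups. The mean was 0.23 and the median -0.091, opposite in sign (camera adjusted p = 0.947 by limma). After the fact, WNT8A (0.17 ± 0.063) rose and TBXT (-0.34 ± 0.068), MESP2 (-0.21 ± 0.073) and EOMES (-0.18 ± 0.063) fell. Of 13 definitive endoderm genes, 4 rose, 5 fell and 4 did not pass, also adjusted over the list alone. FOXA3 (-3.27 ± 0.062) and the receptor KIT (-3.16 ± 0.079) fell, GPC1, a glypican of the cell surface, rose by 1.33 ± 0.060, and the difference for GATA4, an endoderm and heart factor, was -0.10 ± 0.080 (limma adjusted p = 0.310). The endoderm mean was -0.41 and its median 0.011, again of opposite sign (camera adjusted p = 0.832 by limma). After the fact, HHEX (1.05 ± 0.077) and FOXA2 (0.26 ± 0.093) and GATA6 rose, TMPRSS2 (-0.99 ± 0.12), SOX7 (-0.51 ± 0.060) and CXCR4 (-0.33 ± 0.070) fell, and PRDM1, FOXA1 and SOX17 did not pass either. The probe sets of GATA6, a factor related to GATA4, disagreed, the one used here at 0.26 ± 0.088 and another at 4.22. Another probe set of CXCR4 was at -1.73.

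Of 24 liver and yolk sac endoderm secretory genes, 1 rose, 5 fell and 18 did not pass (1 rose and 3 fell adjusted over the list alone). The gene that rose was AFP (alpha-fetoprotein), from 6.23 ± 0.057 to 6.57 ± 0.10 (SD, n = 3), below background in both groups (limma adjusted p = 0.0020). ALB (albumin) was at 5.35 ± 0.057 and 5.23 ± 0.22 (limma adjusted p = 0.371). The apolipoprotein genes APOC1 and APOE fell (-3.19 ± 0.059 and -2.84 ± 0.12), and CEBPA fell by 0.49 ± 0.070. The list's mean was -0.29 (camera adjusted p = 0.688 by limma), with 3 members above background in hESC (APOE, APOC1 and TTR) and 2 in hESC-MEC (APOE and TTR). After the fact, AHSG (-0.26 ± 0.093) and FGG (-0.20 ± 0.073) fell and TTR did not pass. Among 19 enzymes of drug metabolism and the urea cycle, 4 rose, 3 fell and 12 did not pass, also adjusted over the list alone. CYP1B1 (5.25 ± 0.17) and NQO1 (2.78 ± 0.065) rose and the urea cycle enzyme ASS1 fell by 0.79 ± 0.055. Their mean of 0.35 and median of -0.049 differed in sign (camera adjusted p = 0.795 by limma), and the mean was -0.011 without probe sets marked _x_at or _s_at. After the fact, CYP2E1 (0.63 ± 0.079) and ASL (0.53 ± 0.067) rose, and GSTP1 (-0.49 ± 0.066) and CPS1 (-0.34 ± 0.086) fell.

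**Figure D3:**
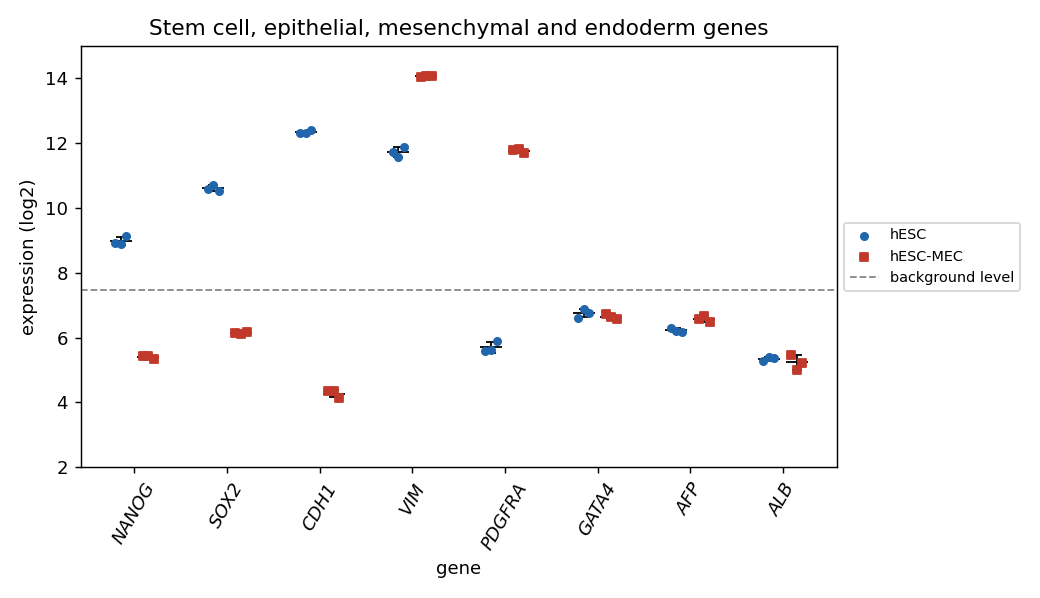
Expression on the log2 scale (vertical axis) of stem cell, epithelial, mesenchymal and endoderm genes (horizontal axis); circles are the 3 hESC arrays, squares the 3 hESC-MEC arrays, short bars with whiskers the mean and SD, and the dashed line the background level of 7.46. NANOG, SOX2 and CDH1 crossed the line downward and PDGFRA upward, while GATA4, AFP and ALB stayed below it in both groups.

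Markers of other cell types mostly fell or did not pass. Several that led the falls were well above background in hESC already, among them OTX2 (12.11), NES (12.25), TFAP2C (8.72) and KDR (8.56). Their falls show expression lost from the stem cells, and do not tell whether neural, trophoblast or endothelial cells were present. Of 23 neural markers, none rose, 13 fell and 10 did not pass, also adjusted over the list alone. OTX2, the filament gene NES (-4.07 ± 0.10) and SOX11 (-2.88 ± 0.10) led the falls, and the mean of -1.14 was lower than that of other genes (camera adjusted p = 0.0067 by limma; adjusted p = 0.333 with an estimated correlation). Of 9 neural crest markers, 3 rose, 2 fell and 4 did not pass, with ETS1 at 3.01 ± 0.10, TFAP2A at 2.89 ± 0.075 and the receptor NGFR at -1.67 ± 0.15 (mean 0.49, camera adjusted p = 0.436 by limma; the mean was -0.026 with the mean over probe sets and -0.098 without those marked _x_at or _s_at). After the fact, SOX9 (0.29 ± 0.086) rose, SOX10 (-0.20 ± 0.058) fell, and PAX7, ERBB3, TFAP2B and PAX3 did not pass. ERBB3 was lower and passed with the mean over probe sets (-1.61) and without probe sets marked _x_at or _s_at (-4.19, limma adjusted p = 9.20e-09), so its result depends on the probe set. Of 16 trophoblast and amnion markers, 4 rose, 5 fell and 7 did not pass. TFAP2C fell by 3.64 ± 0.086, HLA-G rose by 1.19 ± 0.068 and GABRP fell by 1.09 ± 0.093. HLA-G was read only by probe sets marked _x_at or _s_at, which can bind related transcripts. Since HLA-B and HLA-E rose as well, whether HLA-G itself rose is not settled. The mean of that list was -0.17, its median 0.046 and its camera direction upward (adjusted p = 0.890 by limma). Among genes above background its mean was 0.65, but most members dropped out there, TFAP2C among them, and only 1 rose while none fell. After the fact, GATA2 (1.01 ± 0.10), ELF5 (0.36 ± 0.093) and ERVW-1 (0.33 ± 0.093) rose, and CDX2 (-0.56 ± 0.11), GATA3 (-0.21 ± 0.073) and KISS1 (-0.21 ± 0.075) fell. Of 14 endothelial markers, 1 rose, 7 fell and 6 did not pass. The receptors KDR (-3.50 ± 0.11) and FLT1 (-1.85 ± 0.089) fell with VWF (-0.71 ± 0.10), and the mean was -0.52 (camera adjusted p = 0.299 by limma). Named after the fact, the one that rose was CD34 (0.28 ± 0.078). Of 9 blood cell markers, CD74 fell by 1.80 ± 0.11 and 8 did not pass (mean -0.22, camera adjusted p = 0.890 by limma). Counts adjusted over the list alone were the same for these 4 lists.

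For signalling genes, 11 Nodal pathway ligands and targets gave 3 that rose, 3 that fell and 5 that did not pass. FOXH1 (-5.05 ± 0.10) and the activin receptor ACVR2B (-4.82 ± 0.060) fell, and INHBA, the activin A subunit, rose by 3.60 ± 0.064. Their mean was -0.41 and median -0.014, while the camera direction was upward (adjusted p = 0.890 by limma). After the fact, SMAD7 (1.20 ± 0.095) and SKIL (1.07 ± 0.060) rose, ACVR1B (-0.41 ± 0.065) fell, and NODAL, CFC1, GDF3, LEFTY1 and CER1 did not pass. Of 13 Wnt pathway targets and inhibitors, 5 rose, 5 fell and 3 did not pass. The secreted proteins DKK2 (4.71 ± 0.067) and DKK3 (4.26 ± 0.057) rose and AXIN2, a target of Wnt signalling, fell by 1.53 ± 0.093. The mean of 0.44 and the median of -0.067 differed in sign (camera adjusted p = 0.755 by limma). After the fact, LGR5 (0.99 ± 0.10), SFRP1 (0.44 ± 0.063) and CCND1 (0.43 ± 0.061) rose, WIF1 (-1.36 ± 0.12), ZNRF3 (-0.88 ± 0.071), RNF43 (-0.50 ± 0.079) and NKD2 (-0.50 ± 0.12) fell, and NKD1, LEF1 and NOTUM did not pass. Other probe sets reached 5.62 for LGR5, 1.36 for CCND1 and 1.11 for SFRP1, so the size of these rises depends on the probe set. Counts adjusted over the list alone were the same for both lists. Of 28 HOX cluster genes, 4 rose, 2 fell and 22 did not pass (4 rose and 1 fell adjusted over the list alone). HOXB3 (1.26 ± 0.11), HOXA2 (1.08 ± 0.091) and HOXB2 (0.89 ± 0.11) rose, and 3 members were above background in each group. Named after the fact, those 3 were HOXB2, HOXC5 and HOXC11, HOXD12 (0.24 ± 0.061) rose, and HOXC9 (-0.29 ± 0.093) and HOXB9 (-0.23 ± 0.067) fell. The HOX mean was 0.10 and the median -0.0056 (camera adjusted p = 0.473 by limma).

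Of 36 mitotic and S-phase genes, 35 fell, none rose and 1 did not pass, also adjusted over the list alone. CDT1, which licenses replication origins, fell by 3.57 ± 0.062, the checkpoint kinase BUB1 fell by 3.39 ± 0.075 and CDC6 fell by 3.07 ± 0.094. The mean was -1.90 (camera adjusted p = 6.89e-14 by limma; adjusted p = 0.0892 with an estimated correlation). MKI67, chosen after its values were seen as the 1 member that did not pass, had a difference of -0.00037 ± 0.057 by the probe set used, and its other probe sets reached -0.85. Of 27 genes of double strand break and mismatch repair, 21 fell, 5 rose and 1 did not pass, also adjusted over the list alone. FANCI (-2.57 ± 0.064), CHEK1 (-2.52 ± 0.064) and MSH6 (-2.38 ± 0.057) fell most, and the mean was -0.97 (camera adjusted p = 3.06e-04 by limma; adjusted p = 0.0892 with an estimated correlation). After the fact, LIG4 (1.49 ± 0.093), NBN (0.52 ± 0.060), ATM (0.52 ± 0.071), TP53BP1 (0.43 ± 0.064) and ATR (0.38 ± 0.068) rose, and RAD52 did not pass. Of 22 cell cycle inhibitors and p53 targets, 12 rose, 5 fell and 5 did not pass (13 rose and 6 fell adjusted over the list alone). The kinase inhibitor genes CDKN2B (4.79 ± 0.11) and CDKN2A (2.90 ± 0.10) and the death receptor FAS (3.35 ± 0.085) rose. The mean was 0.63 (camera adjusted p = 0.0672 by limma; 0.0162 without probe sets marked _x_at or _s_at). After the fact, AEN (-1.75 ± 0.065), DDB2 (-1.46 ± 0.072), CDKN1C (-1.25 ± 0.095), SESN1 (-0.74 ± 0.071) and SESN2 (-0.60 ± 0.065) fell, and PMAIP1, MDM2, XPC, CDKN1B and RRM2B did not pass. PMAIP1 was lower and passed in 8 other settings (-0.32 with the mean over probe sets), and MDM2 was higher and passed in 6 (0.35 with the mean over probe sets), with another probe set at 2.18.

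All 12 measured antigen presentation genes rose, also adjusted over the list alone, with B2M (beta-2-microglobulin) at 1.94 ± 0.062, HLA-B at 1.75 ± 0.062 and HLA-E at 1.35 ± 0.073. HLA-B, like HLA-G, was read only by probe sets marked _x_at or _s_at, which can bind related transcripts. The rises of the HLA genes may therefore not be separate results. B2M was at 0.28 and did not pass with the probe set of lowest mean (limma adjusted p = 0.134) or without probe sets marked _x_at or _s_at (limma adjusted p = 0.118). Their mean was 0.94 (camera adjusted p = 8.34e-06 by limma; adjusted p = 0.186 with an estimated correlation). Of 14 imprinted genes, 6 rose, 3 fell and 5 did not pass (7 rose and 3 fell adjusted over the list alone). PLAGL1 (3.68 ± 0.081) and NDN (1.39 ± 0.060) rose and NNAT fell by 1.75 ± 0.14 (mean 0.42, camera adjusted p = 0.133 by limma). After the fact, GRB10 (-1.29 ± 0.061) and PEG3 (-0.43 ± 0.074) fell, and PHLDA2, MAGEL2, SNRPN, GNAS and MEG3 did not pass, although PHLDA2 was higher and passed in 7 other settings. Of 21 glycolysis and hypoxia genes, 16 fell, 2 rose and 3 did not pass. The glucose transporter SLC2A3 (-3.79 ± 0.13) and the enolase ENO2 (-2.89 ± 0.086) fell, and NDRG1 rose by 2.27 ± 0.13. The mean was -0.70 (camera adjusted p = 0.0047 by limma; adjusted p = 0.402 with an estimated correlation). After the fact, VEGFA (0.73 ± 0.12) rose, and ADM, PKM and GAPDH did not pass. Of 16 immediate early and heat shock genes, 12 rose and 4 fell. DUSP1 (3.23 ± 0.061) and JUN (2.18 ± 0.11) rose and ATF3 fell by 2.24 ± 0.079. The mean was 0.85 (camera adjusted p = 0.0050 by limma; adjusted p = 0.523 with an estimated correlation), and the call also ended without probe sets marked _x_at or _s_at (0.113). After the fact, FOSB (-0.35 ± 0.071), IER2 (-0.33 ± 0.057) and DNAJB1 (-0.33 ± 0.060) fell. Of 11 reference genes, 8 fell, none rose and 3 did not pass, and PGK1 (-0.89 ± 0.057), PSMB2 (-0.75 ± 0.056) and POLR2A (-0.74 ± 0.12) fell most. Named after the fact, those that did not pass were SDHA, TFRC and PPIA. Their mean was -0.42 (camera adjusted p = 0.0477 by limma; adjusted p = 0.254 with an estimated correlation), negative also after median centring and a second quantile normalization. That call ended after the second quantile normalization (limma adjusted p = 0.0501) and without hESC replicate 2 or 3 or hESC-MEC replicate 1 or 3, and PSMB2 was higher, at 0.37, without probe sets marked _x_at or _s_at. Counts adjusted over the list alone were unchanged for the glycolysis, immediate early and reference lists.

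Of the 26 lists, 11 passed camera at its preset correlation of 0.01 and none did with an estimated correlation. The second test takes the 4 residual degrees of freedom of the fit, which makes passing hard whatever the correlation. The pluripotency list lost its call at an estimated correlation of -0.018, lower than the preset one. These losses therefore do not show that correlation between genes removed the results. It may have contributed for lists with a higher estimate, such as immediate early genes (0.524). Another probe set of the gene had the opposite sign, with any size, for DPPA4, PDGFRA, FLT1, VWF, CD74, DKK2, AXIN2, BUB1, DUSP1, PSMB2, POLR2A and ALB. With the probe set of lowest mean, the call also ended for DPPA4 (0.098), PDGFRA (-0.16), VWF (0.044) and DKK2 (-0.10), whose values turned, and for TFAP2A (0.094), CD74 (-0.044), DKK3 (0.087), AXIN2 (-0.036), HOXB3 (0.16), BUB1 (-0.21), CDKN2A (0.071), CHEK1 (-0.016), MSH6 (-0.035), PSMB2 (-0.10) and POLR2A (-0.063), and with the mean over probe sets for PSMB2 (-0.042). Of the list genes that passed and were named after the fact, those whose call ended in at least 1 other setting were WNT8A, EOMES, FGG, AHSG, MESP2, KISS1, FOXA2, GATA3, GATA6, HOXB9, SOX9, HOXC9, SOX10, NBN, TP53BP1, CPS1, SOX7, GATA2, CDX2, SKIL, ACVR1B, ATM, ATR, CDKN1C, GRB10, PEG3, DNAJB1, CYP2E1, ELF5, ERVW-1 and SESN2. Of those that did not pass, GATA4, MKI67, NODAL and NKD1 were lower and passed with the mean over probe sets, PKM was higher and passed with it and with the probe set of lowest mean, PAX3 was higher and passed with the probe set of lowest mean, and PRDM1, ADM and CFC1 passed with 1 array left out. Among the ended calls, the value also turned with the probe set of lowest mean for FOXA2, SOX7, GATA2, CDX2, HOXB9, ATM, ATR, TP53BP1, CDKN1C, GRB10 and ELF5.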

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

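The tests of hybridisation spikes, RNA integrity, probe set choice and gene-dense chromosomes were chosen after related values had been seen. Probe sets outside the comparison changed as well. Among the 11721 probe sets without an annotated gene, 2886 changed by limma, 301 of them at least 2-fold higher and 268 at least 2-fold lower. Among the 1801 probe sets with several gene symbols, 975 changed, 132 at least 2-fold higher and 156 at least 2-fold lower.

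A change of 2-fold or more in 3966 genes is wide enough that handling of the arrays or RNA may have contributed. The largest difference among 18 hybridisation spike probe sets was 0.157 on the log2 scale, below the 1 log2 unit set as the limit. This shows only that the spikes read alike in the groups. It cannot decide whether hybridisation contributed, since genes changed in both directions and quantile normalization removes a shift shared by all probe sets. The 3' minus 5' signal differed by 0.293 ± 0.084 (SE) for ACTB and by 0.123 ± 0.027 for GAPDH, which argues against RNA integrity as the whole cause, although other controls, noted after their values were seen, did differ, with -1.37, -0.0064 and 0.0013 for the 3', 5' and middle probe sets of 18S rRNA and 0.25, -0.94 and -0.92 for those of another control without a named transcript here. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes, the real one, for both counts (11698 and 3966); the highest of the others was 0 by limma, with 67 to 150 genes at an unadjusted p below 0.05. Each of the other splits mixed arrays of both groups on each side, so the group difference entered the spread and few calls were possible there. The 10 splits are also too few for a share under 0.05, and the differentiation that the design names stays open, as untested.

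The liver and definitive endoderm lists did not rise as lists, although the cells are described as meso-endoderm. A candidate explanation is that the probe set chosen for a gene missed its rise. Of the 27 list genes with several probe sets whose chosen one did not rise 2-fold, 1 (3.70%, exact 95% interval 0.0937% to 18.97%), GATA6, had another that did, which argues against this for the lists. Endoderm cells could instead be a small share of the cultures: 5 members of the 2 lists (TTR, APOE, GPC1, HHEX and TMPRSS2, noted after their values were seen) were above background in hESC-MEC, but only HHEX and GPC1 rose, APOE and TMPRSS2 fell, TTR did not pass and all but HHEX were above it in hESC already, and no bulk value fixes a share of cells, so this cannot be told apart from endoderm genes not being expressed.

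Chromosome 19 genes were lower, a pattern noticed in these data and tested on them: of 1320 genes, 197 rose and 596 fell, with a mean log2 fold change of -0.33 (camera adjusted p = 0.0305 by limma over chromosomes; adjusted p = 0.546 with an estimated correlation). Without its zinc finger (ZNF) genes, taken by symbol, the mean was -0.29 ± 0.026 (SE over 1100 genes), below the -0.16 of the next lowest chromosome. Its unadjusted camera p was 0.0071 by limma, and 0.0943 with an estimated correlation. That SE takes genes of the same arrays as independent. Genes with ZNF symbols did not carry all of the difference, but zinc finger genes with other symbols stayed in. Random lists matched on mean level averaged -0.040 (95% from -0.098 to 0.016 over 10000 lists), so a trend with signal level did not give a mean this low. Those lists also draw genes as independent, which can make the interval too narrow. Genes of the gene-dense chromosomes 16, 17 and 22 averaged -0.14, below their matched lists (-0.083 to -0.00094), so a trend shared by gene-dense chromosomes may account for part of the pattern, although their camera p was 0.265. GC content was not tested, and no biological explanation was tested.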

How the results depend on the processing

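The settings here were chosen before the data were examined. Changed genes numbered between 10988 and 11456 when each array was left out in turn, against 11698 with all, and between 3955 and 3987 at 2-fold or more, against 3966. Testing all probe sets gave 25667 and 7973 (4151 higher and 3822 lower, where genes gave 1865 and 2101), from more features tested, and genes above the olfactory receptor background gave 7728 and 2704, from fewer. The probe set of lowest mean gave 8695 and 2657, and the mean over probe sets gave 11821 and 3063, from the choice of probe set. The 90 named genes gave 1362 comparisons with the same direction and call, 15 that lost the call in the same direction, 1 that gained it (GATA4 with the mean over probe sets) and 6 reversals. With the probe set of lowest mean, DPPA4 was at 0.098, PDGFRA at -0.16, VWF at 0.044 and DKK2 at -0.10. Without probe sets marked _x_at or _s_at, PSMB2 was at 0.37 (limma adjusted p = 0.0053) and ALB at 0.013. Calls that ended were, with the probe set of lowest mean, those of DPPA4, PDGFRA, VWF, DKK2, COL3A1 (0.18), TFAP2A, CD74, DKK3, AXIN2, HOXB3, BUB1, CDKN2A, CHEK1, MSH6, B2M (0.28), PSMB2 and POLR2A, with the mean over probe sets that of PSMB2, and without _x_at and _s_at probe sets that of B2M (0.28). These changes follow from another probe set standing for the gene; why probe sets differ was not tested.

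The 145 genes named after their values were seen gave 1958 comparisons with the same direction and call, 93 that lost the call in the same direction, 41 that gained it and 87 reversals. After median centring, reversed values were SOX17 -0.0053, FOXA1 -0.0039, RRM2B -0.0012, MEG3 -0.0065, HOXC5 -0.015. After a second quantile normalization, reversed values were SOX17 -0.0053, BMP7 -0.0013, MEG3 -0.0090, HOXC5 -0.020. With array weights, reversed values were SOX17 -0.038, MKI67 0.0085, FOXA1 -0.0014. With the mean over probe sets, reversed values were SOX17 -0.068, PRDM1 -4.56e-05, FOXA1 -0.081, ERBB3 -1.61, BMP7 -0.89, GNAS -0.050, MEG3 -0.054, PPIA 0.024. With the probe set of lowest mean, reversed values were CD9 -0.39, TAGLN -0.12, FOXA2 -0.091, SOX17 -0.15, SOX7 0.093, GATA2 -0.10, CDX2 0.10, HOXB9 0.023, ATM -0.11, ATR -0.12, TP53BP1 -0.082, CDKN1C 0.10, GRB10 0.054, CFC1 0.068, FOXA1 -0.17, PAX7 0.029, ERBB3 -0.059, TFAP2B -0.0059, ELF5 -0.0029, LEF1 0.016, BMP7 -1.35, MEG3 -0.14, GAPDH 0.088, TFRC -0.034, PPIA 0.078, ITGB8 0.17, ITGB4 0.030. Without _x_at and _s_at probe sets, reversed values were TAGLN -0.12, ERBB3 -4.19, PHLDA2 -0.060, GNAS -0.040, PPIA 0.078, ITGB4 0.030. With an array left out, lowest and highest values on both sides of 0 were FOXD3 -0.11 to 0.042, SOX17 -0.13 to 0.10, MKI67 -0.023 to 0.014, GDF3 -0.024 to 0.16, CER1 -0.075 to 0.053, FOXA1 -0.078 to 0.090, TFAP2B -0.0070 to 0.11, PAX3 -0.035 to 0.077, LEF1 -0.14 to 0.017, NOTUM -0.10 to 0.049, ID2 -0.10 to 0.041, BMP7 -0.041 to 0.054, RRM2B -0.019 to 0.055, MAGEL2 -0.010 to 0.077, SNRPN -0.063 to 0.13, MEG3 -0.054 to 0.082, PKM -0.022 to 0.16, SDHA -0.078 to 0.0010, HOXC5 -0.024 to 0.032. The call ended, turned values included and with the number of settings in parentheses, for WNT8A (11), EOMES (9), FGG (9), AHSG (7), MESP2 (6), KISS1 (6), S100B (6), FOXA2 (5), GATA3 (5), GATA6 (4), HOXB9 (4), SOX9 (3), HOXC9 (3), SOX10 (2), NBN (2), TP53BP1 (2), CPS1 (2), ITGB4 (2), SOX7 (1), GATA2 (1), CDX2 (1), SKIL (1), ACVR1B (1), ATM (1), ATR (1), CDKN1C (1), GRB10 (1), PEG3 (1), DNAJB1 (1), CLDN11 (1), ZNF503 (1), CYP2E1 (1), ELF5 (1), ERVW-1 (1), SESN2 (1), ITGA2B (1), ITGB8 (1). It was gained in the same direction for PMAIP1 (8), PHLDA2 (7), MDM2 (6), BMP2 (6), FOXD3 (2), MKI67 (2), NKD1 (2), PKM (2), NODAL (1), PAX3 (1), PRDM1 (1), ADM (1), CFC1 (1), ERBB3 (1). Of the reversed values of genes that did not pass, those of CD9 with the probe set of lowest mean, ERBB3 with the mean over probe sets and without _x_at and _s_at probe sets, and BMP7 with the mean and the probe set of lowest mean did pass. Why these differ was not tested.

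List means that changed sign were those of trophoblast markers, at 0.65 among genes above background, of neural crest markers, at -0.026 with the mean over probe sets and -0.098 without _x_at and _s_at probe sets, and of drug metabolism enzymes, at -0.011 without those probe sets. None of these means passed camera. The trophoblast mean of 0.65 rested on the few members above background, without TFAP2C. BMP and TGF-beta targets, ligands and antagonists, tested as 1 list, passed after median centring (1.18) and without _x_at and _s_at probe sets (1.45). With an array left out their mean lay between 1.13 and 1.25, and they passed without hESC replicate 1 (limma adjusted p = 0.037, range 0.0212 to 0.523 over the camera settings). Without _x_at and _s_at probe sets, the p53 target list passed (0.87) and the immediate early list did not (0.80). The reference gene list no longer passed without the lowest 40% of genes (-0.42), among genes above background (-0.42), after a second quantile normalization (-0.42), with array weights (-0.41), with the mean over probe sets (-0.20), with the probe set of lowest mean (-0.054) and without _x_at and _s_at probe sets (-0.40). With an array left out its mean lay between -0.44 and -0.41, and the call ended without hESC replicate 2 or 3 or hESC-MEC replicate 1 or 3. The cause was not tested.

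No list passed camera with an estimated correlation. That setting takes the 4 residual degrees of freedom of the fit, so the lost calls cannot be put down to correlation between genes. The means of the lists that lost the call were -3.25 for pluripotency, 1.37 for early mesoderm, 4.36 for mesenchymal genes, -3.33 for epithelial junctions, -1.14 for neural markers, -1.90 for mitotic genes, -0.97 for DNA repair, 0.94 for antigen presentation, -0.70 for glycolysis, 0.85 for immediate early and -0.42 for reference genes. The estimated correlation itself lay between -0.094 and 0.524. Fry, which asks whether a list moves and not whether it differs from other genes, passed for all 26 lists in a common direction and in mixed directions. The lists it added were Nodal pathway (-0.41), primitive streak (0.23), definitive endoderm (-0.41), liver (-0.29), drug metabolism (0.35), keratins (-1.20), neural crest (0.49), trophoblast (-0.17), endothelial (-0.52), blood (-0.22), Wnt (0.44), BMP and TGF-beta (1.20), HOX (0.10), p53 targets (0.63) and imprinted genes (0.42).

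The replicate number as a block gave 11479 changed genes and 3966 at 2-fold or more. Same-numbered arrays deviated from their group means with correlations of -0.065, 0.015 and -0.025 across genes, where hESC replicate 3 and hESC-MEC replicate 1 gave 0.069. No pairing by number was detectable, but so few arrays cannot show that the samples were unpaired. With the block, the reference gene list (-0.42) did not pass (limma adjusted p = 0.0528), and no other list and no gene named by the rule changed its call; of the genes named later, EOMES, WNT8A, FGG and AHSG lost it and BMP2 and PHLDA2 gained it. Changes of genes near background are limited by the signal of the array: 10324 of 19775 genes were above background in either group.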

Other observations

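Gene families were defined by symbol, and some passed camera at its preset correlation, whereas none passed with an estimated one. The counts of changed genes below are to be read against the 59.2% of all genes that changed. Some families share members with the fixed lists, among them the collagens, S100 genes, claudins and cadherins, so they are not independent of those lists. Family examples were named after the values were seen. No mean below changed sign after median centring or a second quantile normalization. Of 43 collagens, 20 rose and 10 fell. COL5A2, a fibrillar collagen, rose by 6.40 ± 0.15 (log2 fold change, SE, n = 3 arrays per group), whereas COL9A3 (-4.23 ± 0.15), COL4A6 (-2.82 ± 0.084) and COL2A1, the main cartilage collagen (-1.57 ± 0.094), fell. The collagen mean was 1.31 (camera adjusted p = 0.0044 by limma over 21 families; adjusted p = 0.172 with an estimated correlation). Of 25 integrins, 12 rose and 5 fell (mean 0.66, camera adjusted p = 0.0276 by limma; adjusted p = 0.175 with an estimated correlation), with ITGA4 at 2.93 ± 0.13 and ITGA6 at -1.87 ± 0.062. ITGA2B (-1.76 ± 0.067), ITGB8 (-0.89 ± 0.091), ITGB4 (-0.89 ± 0.081) and ITGA7 (-0.40 ± 0.11) were the other integrins that fell, although with the probe set of lowest mean the calls ended for ITGA2B (-0.030), ITGB8 (0.17) and ITGB4 (0.030), the last also without probe sets marked _x_at or _s_at. Of 20 S100 genes, 8 rose and 2 fell (mean 1.01, camera adjusted p = 0.0061 by limma; adjusted p = 0.175 with an estimated correlation), with S100A4 at 3.51 ± 0.089, S100A11 at 3.35 ± 0.063 and, as the 2 that fell, S100A14 at -1.10 ± 0.091 and S100B at -0.21 ± 0.072, whose call ended in 6 other settings. Adhesion genes changed in both directions: CLDN11 rose by 4.04 ± 0.14 and CLDN6 fell by 6.20 ± 0.066, and CDH11 rose by 5.45 ± 0.064 where CDH3 fell by 3.84 ± 0.091. The call of CLDN11 ended with the probe set of lowest mean (0.031), as did that of ZNF503 (0.17), a zinc finger gene. Neither claudins (15 of 21 changed; mean -0.55; camera adjusted p = 0.266 by limma) nor cadherins (10 of 21 changed; mean -0.065; camera adjusted p = 0.598 by limma) passed as families.

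Of 8 metallothioneins, which bind zinc and copper, 7 rose and none fell, with MT2A at 1.93 ± 0.081 and MT1E at 1.15 ± 0.10 (mean 0.95, camera adjusted p = 0.0034 by limma; adjusted p = 0.396 with an estimated correlation). Their probe sets are similar in sequence and can share transcripts. Of 77 mitochondrial ribosomal protein genes, 54 fell and 11 rose, with MRPS9 at -1.43 ± 0.055 and MRPL24 at 1.35 ± 0.065 (mean -0.37, camera adjusted p = 5.40e-04 by limma; adjusted p = 0.172 with an estimated correlation). Of 57 cytosolic ribosomal protein genes, 15 changed (mean -0.060, camera adjusted p = 0.642 by limma). Of 466 ZNF genes, 273 fell and 66 rose, with ZNF850 at -3.92 ± 0.073 and ZNF503 at 5.31 ± 0.16 (mean -0.45, camera adjusted p = 2.49e-04 by limma; adjusted p = 0.175 with an estimated correlation). Of 55 histone genes, 21 rose and 7 fell, with H2AC6 at 2.87 ± 0.078 and H1-10 at -1.30 ± 0.067 (mean 0.36, camera adjusted p = 0.0301 by limma; adjusted p = 0.280 with an estimated correlation). Interferon-induced genes (20 of 25 changed) and complement components (12 of 20 changed) each had a camera adjusted p of 0.0913 by limma, with IFI16 at 6.20 ± 0.18, ISG15 at -1.37 ± 0.19, C1S at 4.61 ± 0.10 and C3 at -1.32 ± 0.062. The other 9 families did not pass, with camera adjusted p from 0.288 to 0.828 by limma. Genes that changed were 15 of 48 protocadherins, 6 of 23 MAGE and GAGE genes, 209 of 376 solute carriers, 20 of 32 complex I subunits, 23 of 34 proteasome subunits, 15 of 24 ephrins and Eph receptors, 11 of 31 serpins, 32 of 59 TRIM genes and 5 of 11 small nucleolar RNA host genes, the last being SNHG33 (-1.32 ± 0.068) and SNHG17 (-0.44 ± 0.066), which fell, and SNHG18 (0.87 ± 0.068), SNHG28 (0.51 ± 0.061) and SNHG32 (0.29 ± 0.063), which rose. Of these 9 families, complex I subunits, proteasome subunits, and ephrins with Eph receptors lay above the 59.2% of all genes that changed. The rest lay below it.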
